A study of Mus musculus with 18 samples.

How the data were processed

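Gene expression was measured by mRNA sequencing of 18 mouse libraries in 6 groups of 3 replicates. The groups were feeders labelled control, feeders labelled p53-defective, embryonic stem (ES) cells on each kind of feeder, ES cells labelled as cultured on control feeders with the feeders removed, and ES cells with ATN161 in place of feeders. The label does not say whether the former were separated from feeders or grown without them. Per the labels, RNA was isolated with Trizol and libraries were built with a TruSeq mRNA kit. Whether the libraries kept the strand of the RNA is not stated. The submitters' processing notes name HISAT2 2.1.0, SAMtools 1.4, StringTie 1.3.3b and DESeq2 1.2.10 without their roles, and the builds mm10 and GRCm38, which are 2 names of the same assembly.

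The deposited table holds expected counts, that is estimated read counts that were not normalised, for 75416 RefSeq mRNA transcripts. Of these, 32625 were curated (NM) and 42791 predicted (XM) models. Counts were summed over the transcripts of each Entrez gene to 19630 genes and rounded. Of the sums above 0, 89.3% were whole within 0.05. For 19482 genes the symbol and position came from the RefSeq annotation of GRCm38, and 148 had no symbol there. The deposited FPKM, TPM, normalised counts and group averages were not used. Reads of multicopy families and of pseudogenes cannot be assigned to 1 locus with certainty, which applies to the Zscan4 and Usp17l families, Eno1b, Hmga1b, genes whose symbol ends in -ps or -ps1, the Oas and Ifi200 families, Pou5f1 and Nanog.

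Library totals were 15.12 to 19.83 M (mega) counts, so that 1 count was below 0.1 CPM (counts per M) in each library. Intervals and floors from counts cover counting error only. Genes were filtered with filterByExpr, which kept 15389 and removed 4241. Differences were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (TMM scaling, robust fit, two-sided), with all 18 libraries in 1 fit and 1 coefficient per group. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over the genes tested, and changes of at least 2-fold were also counted. Fold changes are on the log2 scale, each with its standard error (SE), and levels are TMM-scaled CPM as mean and SD of 3 libraries. A prior count of 2 was used for the log2 CPM of the principal components and the list tests, not for the fold changes. The common biological coefficient of variation was 0.0792, and correlations between replicates were 0.9947 to 0.9986. The replicate differences per degree of freedom were 1.94 to 42.15 times those of counting alone, over genes with at least 20 summed counts. Where a group had no counts, a fold was computed against a floor of 3 counts over the group and written as "at least". The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these libraries.

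Gene lists for pathways and cell types were written before the data were examined, as were the comparisons, tests, alternatives and the rule for named genes. Members tested and at 1 CPM or more in a compared group were tested together with camera in limma 3.58.1 (preset correlation 0.01, lists of at least 5 members, Benjamini-Hochberg over the lists of a comparison). The same test with an estimated correlation and fry were run beside it. With the preset correlation 85 list calls were made over the 5 pairwise comparisons, and 7 of them remained with an estimated correlation. Counts of members are over all genes tested; counts adjusted over the list alone are given where they differ.

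Genes were named by rule: the p53, fibronectin, integrin and pluripotency genes given in every comparison, the 8 largest rises and 8 largest falls among called genes with groups that did not overlap and a mean of at least 10 CPM in a group (predicted models and genes without a symbol left out), the same among ES-specific genes for ES cell cultures, and up to 4 members with the smallest p of each list described. From these sets, the text names those that fit its lists. Groups of 3 and 3 libraries fail to overlap by chance in 10% of genes.

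ES-specific genes were at least 8-fold higher in both groups of ES cells without feeders than in both feeder groups, and feeder-specific genes the reverse, with at least 10 CPM. Their levels in co-culture were taken relative to the pure groups with an offset of 0.5 CPM and compared by an exact permutation test, whose smallest p with 3 against 3 libraries is 0.1. Comparisons without a shared library were set side by side by the correlation of their log2 fold changes across genes.

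Alternatives were size factors of DESeq2 1.42.0, its Wald test, limma-voom, no filter on low counts, a filter of 5 CPM in 3 libraries, a replicate block, a fit of only the 2 groups compared, leaving out each library in turn, scaling on ES-specific genes, folds of 4 and 32 for specific genes, and tests within ES-specific or feeder-specific genes alone. Fits within ES-specific genes for the 3 comparisons of ES cells with the feeders removed or replaced, TMM-scaled CPM for the specific genes, and lists with all tested members were added after the data were seen.

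The fit was tested on simulated data with the observed depths and spread. In the feeder comparison (15266 genes), 76.1% of simulated 1.5-fold changes, 91% of 2-fold and 100% of 4-fold changes were called. The values were 70.1%, 95.5% and 100% for ES cells on the 2 kinds of feeder (15247 genes), and 82.1%, 92.5% and 100% for feeder removal (15265 genes). They were 80.6%, 91% and 97% for ATN161 against control feeders (15266 genes), and 70.1%, 98.5% and 100% for ATN161 against feeder removal (15259 genes). Of unchanged genes, 0.09%, 0.08%, 0.07%, 0.06% and 0.05% were called, in the same order. Most simulated genes were unchanged between the groups compared, whereas 52% to 83.4% were called in the real comparisons. These rates therefore do not cover errors of scaling where most genes or the mixture change.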

Results

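Messenger RNA was sequenced in 18 mouse libraries, 3 in each of 6 groups. Embryonic fibroblasts used as feeders, a cell layer that supports embryonic stem (ES) cells in culture, were sequenced alone, either control feeders or feeders labelled p53-defective. ES cells were sequenced together with each kind of feeder, after removal of control feeders, and with ATN161, an inhibitor of integrin α5β1, in place of feeders. Library totals were 18.62 to 19.34 M (mega) counts for ES cells on control feeders, 19.06 to 19.15 M on feeders labelled p53-defective, 17.48 to 17.71 M for control feeders and 15.12 to 16.71 M for feeders labelled p53-defective. They were 17.66 to 18.11 M after feeder removal and 19.31 to 19.83 M with ATN161. On the first principal component, which held 61.4% of the variance, ES cells on control feeders (-96.07 to -94.55) lay on the side of ES cells without feeders. ES cells on feeders labelled p53-defective (66.75 to 74.23) lay on the side of the feeders. By the series title, the study is about feeder p53, fibronectin, integrins and ES cell pluripotency. For every gene named below with a test, the 3 libraries of one group all lay above or all below the 3 of the other, except where overlap is stated. On GRCm38, the p53 gene Trp53 lies on chromosome 11 from 69580348 to 69591873, the fibronectin gene Fn1 (Entrez 14268) on chromosome 1 from 71585473 to 71653280, and the integrin α5 gene Itga5 (Entrez 16402) on chromosome 15 from 103344286 to 103366791.

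The first comparison, of the feeders alone, asks what sets the feeders labelled p53-defective apart before ES cells are added. Trp53 RNA was present in every feeder library and was higher in the feeders labelled p53-defective, at 296 ± 45 against 119 ± 6.8 CPM (mean ± SD, n = 3 per group; 326, 317 and 244 against 123, 124 and 112), a log2 fold change of 1.31 ± 0.09 (SE, adjusted p = 1.07e-11). The label does not say which alteration of p53 the cells carry. RNA of p53 target genes was lower: Cdkn1a, which encodes the cell cycle inhibitor p21, fell 2.55-fold (260 ± 65 against 664 ± 16 CPM, adjusted p = 4.6e-10), and Mdm2, which encodes the ubiquitin ligase of p53, fell 2.67-fold (164 ± 13 against 437 ± 8.4 CPM, adjusted p = 2.01e-14). Of 35 measured p53 targets, 24 fell and 6 rose (25 and 6 adjusted over the list alone), with a median log2 fold change of -1.02 and an adjusted p of 0.000992 (adjusted p = 0.225 with an estimated correlation). Among them were the antiproliferative gene Btg2 (-1.77 ± 0.08), the desmosomal gene Perp (-2.24 ± 0.11) and the BH3-only gene Pmaip1 (-1.70 ± 0.09).

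Cell cycle genes rose in the feeders labelled p53-defective. All 24 G2/M genes measured rose (median 1.90, adjusted p = 1.34e-11; adjusted p = 0.0627 with an estimated correlation), among them the spindle genes Tpx2 (2.62 ± 0.08) and Kif11 (2.55 ± 0.08) and the topoisomerase gene Top2a (2.16 ± 0.08). Of 24 DNA replication genes, 21 rose and 2 fell (median 1.32, adjusted p = 7.65e-07; adjusted p = 0.302 with an estimated correlation). The licensing factor Cdt1 stood at 1.93 ± 0.08 and the polymerase gene Pole at 1.82 ± 0.08. Of 23 glycolysis and hypoxia genes, 17 rose and 2 fell (median 0.82, adjusted p = 0.000992; adjusted p = 0.302 with an estimated correlation). Ndrg1 stood at 2.99 ± 0.10 and the angiogenic factor Vegfa at 1.46 ± 0.09. Of 20 integrated stress response genes, 18 rose and 1 fell (median 1.26, adjusted p = 0.000176; adjusted p = 0.387 with an estimated correlation), with the amino acid synthesis genes Psat1 (1.57 ± 0.10) and Asns (1.48 ± 0.10) up and Sesn2, also a p53 target, down (-1.32 ± 0.09). All 5 measured genes of the 2-cell-like list, which marks a rare early-embryo-like state of ES cells, rose (adjusted p = 0.000196; adjusted p = 0.0453 with an estimated correlation). Their median was 7.78, or 5.14 with genes at 0 counts set to their bound. Their levels stayed low, as with Usp17la at 5.72 ± 0.68 against 0.0193 CPM and Zscan4f at 2.71 ± 0.26 CPM against none. Only 5 of the 18 list genes reached 1 CPM in a feeder group, the cut for list members. Usp17la and Zscan4f did so only in the feeders labelled p53-defective, so with that cut they could only rise. The count of 5 and the list p were thus in part set by the cut.

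Matrix and fibroblast genes were lower in the feeders labelled p53-defective, although Fn1 was not among them. Fn1 stood at 14200 ± 1600 against 12700 ± 1200 CPM (log2 fold change 0.16 ± 0.14, adjusted p = 0.291), with overlap between the groups. Of 27 interstitial matrix genes, 26 fell and none rose (median -2.39, adjusted p = 2.87e-09; adjusted p = 0.302 with an estimated correlation). The elastin gene Eln stood at 0.0608 against 567 CPM, the proteoglycan gene Lum at 0.0601 against 271 CPM, and the matricellular gene Postn (-10.91 ± 0.19) at 3.06 against 5920 CPM. Of 24 fibroblast markers, 21 fell and 1 rose (21 and 2 adjusted over the list alone; median -2.56, adjusted p = 5.3e-07; adjusted p = 0.166 with an estimated correlation). Thy1 stood at -4.82 ± 0.11 and the growth factor receptor gene Pdgfrb at -5.23 ± 0.14. Of 20 matrix remodelling genes, 14 fell and 4 rose (median -1.38, adjusted p = 0.005; adjusted p = 0.415 with an estimated correlation). The protease inhibitor Serpine2 stood at -4.46 ± 0.11 and the metalloproteinase Mmp14 at -4.15 ± 0.11. Of 24 feeder-secreted factors, 19 fell and 3 rose (median -1.77, adjusted p = 0.000901; adjusted p = 0.328 with an estimated correlation). Igfbp3 stood at -3.80 ± 0.12. Of 19 mesothelial markers, a set chosen only after the data were seen, 15 rose, with Msln at 775 ± 96 against 28.1 ± 3.1 CPM and Wt1 at 112 ± 9.2 against 0.747 ± 0.21 CPM.

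Integrin genes were more often lower than higher: 10 of 15 fell and 3 rose (median -0.85, adjusted p = 0.0488; adjusted p = 0.548 with an estimated correlation). The collagen receptor gene Itga11 stood at -6.52 ± 0.12 and Itga8 at -8.70 ± 0.24. This list call ended without control feeder replicate 3 (median -0.66, adjusted p = 0.0504). Itgb1, the β1 chain of the fibronectin receptor, fell by 0.57 ± 0.08 on the log2 scale (adjusted p = 1.2e-06), and Itgav stood at -0.20 ± 0.12 (adjusted p = 0.143; called at -0.21 in a fit of only these 2 groups). Itga5 stood at -0.19 ± 0.09 (adjusted p = 0.0445) with overlap between the groups, and that call ended without control feeder replicate 2 (-0.10) or 3 (-0.18), without replicate 1 (-0.05) or 2 (-0.12) of the feeders labelled p53-defective, and with DESeq2 size factors (-0.16).

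Immune and lipid genes formed further groups. Of 20 interferon response genes, 19 fell and none rose (median -3.56, adjusted p = 3.51e-09; adjusted p = 0.128 with an estimated correlation). Oasl2 stood at -5.93 ± 0.14, the ubiquitin-like modifier Isg15 at -4.57 ± 0.13 and Stat2 at -2.73 ± 0.09. Of 20 cholesterol synthesis genes, 19 fell and 1 rose (median -2.19, adjusted p = 7.79e-07; adjusted p = 0.355 with an estimated correlation). Hmgcs1 stood at -3.01 ± 0.10. Of 14 macrophage markers, 12 fell and 2 rose (median -8.73, or -5.79 with genes at 0 counts set to their bound; adjusted p = 0.000235, and adjusted p = 0.0788 with an estimated correlation). The lysozyme gene Lyz2 stood at 0.0404 against 113 CPM, and the antigen presentation gene Cd74 rose by 4.85 ± 0.14. These markers were thus measured in the control feeders beside the fibroblast genes.

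Some changes in this comparison were near complete. Genes with 0 counts in the feeders labelled p53-defective were at least 2253-fold (Lgr5, a WNT target gene), 2162-fold (Apod), 1405-fold (Cthrc1), 1242-fold (Irx1) and 1115-fold (Fgl2) lower than in control feeders. Igfbp5 fell from 2310 ± 230 to 0.125 ± 0.11 CPM. In the other direction, the endoderm transcription factor gene Foxa2 stood at 11.5 ± 2 against 0.0189 CPM, Pkhd1l1 rose by 8.85 ± 0.18 (800 ± 87 CPM), and the interferon-inducible gene Ifi202b stood at 112 ± 27 against 0.0189 CPM. With edgeR, 11433 of 15389 genes were called, 5528 higher and 5905 lower, of which 2360 and 3193 changed at least 2-fold. The 2 feeder groups differ by their label alone, so that p53, the origin of the cells and the day of culture cannot be told apart from these values.

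**Figure D1:**
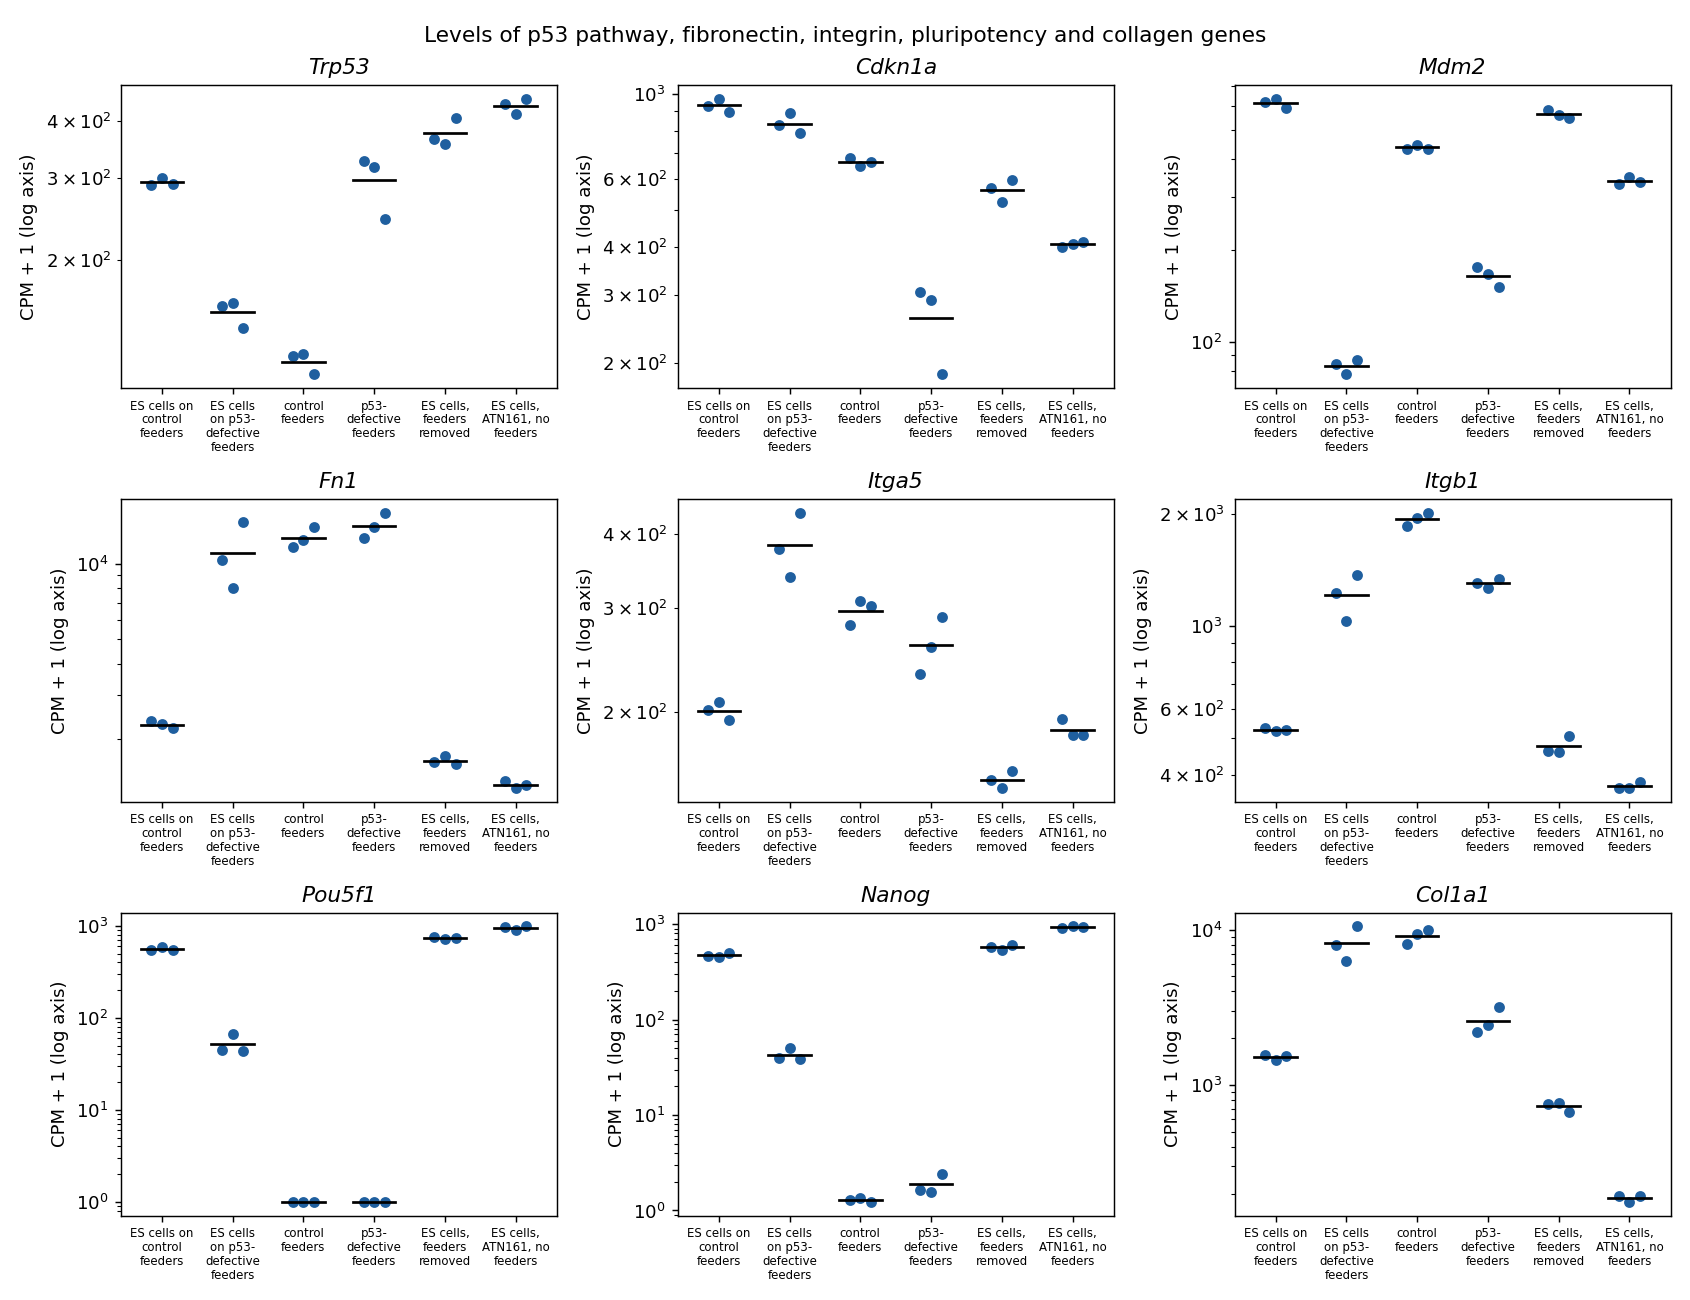
Levels of 9 genes in the 6 groups as TMM-scaled CPM plus 1 on log axes, with 1 point per library and a bar at the mean of 3. In ES cells on feeders labelled p53-defective, Pou5f1 had a mean of 50.9 CPM against 557 on control feeders, while Fn1 had 11000 against 2290.

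The second comparison, of ES cells on the 2 kinds of feeder, asks how ES cells respond to the p53 label of their feeders, but each library holds RNA of ES cells and feeders together. ES cell transcripts were far lower on feeders labelled p53-defective. Pou5f1 (Oct4), a core pluripotency factor, fell 11-fold (50.9 ± 13 against 557 ± 23 CPM, n = 3 per group, adjusted p = 1.18e-14), Nanog 11.3-fold (41.9 ± 6.9 against 472 ± 19 CPM, adjusted p = 6.38e-18) and Sox2 16.6-fold (15.4 ± 3.6 against 255 ± 6.1 CPM, adjusted p = 5.49e-17). Fn1 rose 4.82-fold (11000 ± 3400 against 2290 ± 80 CPM, adjusted p = 1.69e-12), and the fibronectin receptor genes rose, Itga5 1.91-fold, Itgb1 2.3-fold and Itgav 1.55-fold. In feeders alone Fn1 stood at 12700 (control) and 14200 CPM.

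The mixture itself may have differed. In ES cells on control feeders, the 408 ES-specific genes stood at a median of 84.6 ± 0.3% of their level after feeder removal. On feeders labelled p53-defective they stood at 8.03 ± 0.38% (mean ± SD, n = 3), a difference of -3.40 on the log2 scale. The 47 feeder-specific genes stood at 11.9 ± 0.15% and 40.9 ± 5.7% of their level in feeders alone, a difference of 1.78. Each difference gave p = 0.1 in a two-sided exact permutation test, the smallest p that 3 against 3 libraries allow. These percentages are not shares of a library. Feeder-specific genes stood at 8% after feeder removal, and ES-specific genes at 2.73% (control) and 2.53% in feeders alone. With a 4-fold cutoff feeder-specific genes stood at 24.2% and 65.4%. On feeders labelled p53-defective the feeder-specific value thus moved with the cutoff. The 2 values can therefore not be added to ask whether a change of share alone gives both. With edgeR, 12829 of 15389 genes were called, 5638 higher and 7191 lower, of which 2773 and 4532 changed at least 2-fold. When scaled on ES-specific genes, the split was 13556 higher and 377 lower, since that scaling moved the median of all genes from -0.18 to 3.25. For the other comparisons it moved the median to 0.34 (feeders, from -0.01), -0.27 (feeder removal, from -0.01), -0.36 (ATN161 against control feeders, from 0.07) and -0.15 (ATN161 against feeder removal, from 0.03).

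**Figure D2:**
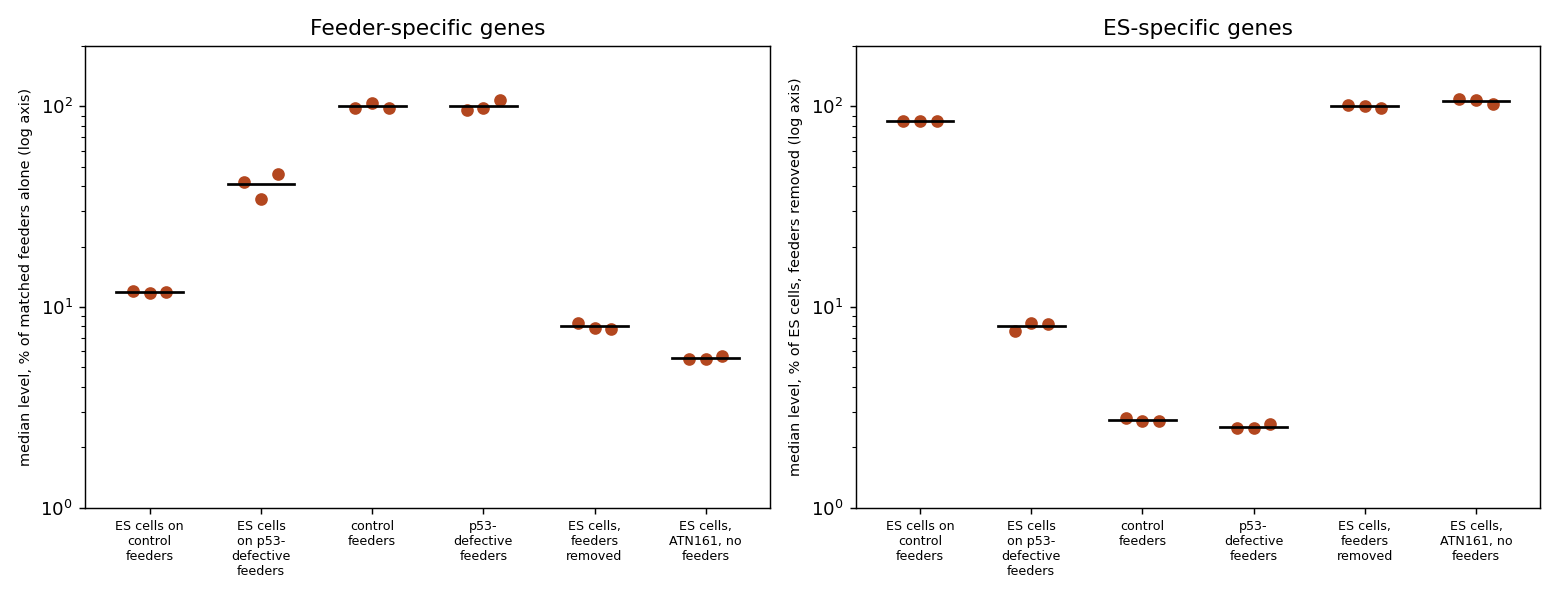
Median level of the feeder-specific and ES-specific genes per library, in percent of their level in the pure groups, with 1 point per library of the 6 groups. ES-specific genes stood at 8.03% on feeders labelled p53-defective and at 84.6% on control feeders.

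Pluripotency genes fell as a group when scaled on all genes. All 14 core pluripotency genes fell (median -3.64, adjusted p = 1.06e-05; adjusted p = 0.0551 with an estimated correlation), all 23 naive pluripotency genes fell (median -3.32, adjusted p = 6.21e-08; adjusted p = 0.0551), and all 18 ES cell markers fell (median -3.80, adjusted p = 7.81e-07; adjusted p = 0.0929), the p-values given second being those with an estimated correlation. Most ES cell markers, among them Pou5f1, Nanog, Sox2 and Esrrb, are also in the core or naive list, so these calls are not separate results. The nuclear receptor gene Esrrb fell by 4.33 ± 0.09 and the T-box gene Tbx3 by 4.80 ± 0.10 on the log2 scale. Within the ES-specific genes, scaled on them, 140 of 408 were higher and 154 lower, and 60 and 63 of these differed at least 2-fold. On that scale Pou5f1 (-0.03 ± 0.10, adjusted p = 0.758) and Nanog (-0.07 ± 0.10, adjusted p = 0.517) were not called, whereas Sox2 (-0.63 ± 0.12), Esrrb (-0.90 ± 0.09) and Tbx3 (-1.37 ± 0.13) were lower. Dnmt3l (2.82 ± 0.12) and Dppa3 (1.18 ± 0.15) were higher. Of 13 ES-specific core members 2 were higher and 7 lower (median -0.33), and of 17 naive members 5 were higher and 10 lower (median -0.44). Klf2 turned from -3.32 ± 0.10 to 0.10 ± 0.11 (not called) and the naive list had a median of 0.10 over its 23 members. That list stayed called (adjusted p = 1.94e-14) and below the median of all genes on that scale, 3.25. Large falls among ES-specific genes were those of the podocyte gene Nphs1 (-5.94 ± 0.19), the zinc finger gene Sall1 (-5.87 ± 0.12), the threonine dehydrogenase gene Tdh (-5.83 ± 0.14) and the hormone gene Trh (-5.77 ± 0.16). All 11 measured 2-cell-like genes fell (median -1.57, adjusted p = 0.00651; adjusted p = 0.0929 with an estimated correlation). Usp17la stood at -2.29 ± 0.11 and Zscan4d at -1.94 ± 0.11. On ES-specific scaling that list had a median of 1.86 and its call ended (adjusted p = 0.326), and Usp17la turned to 1.15 and Zscan4d to 1.49.

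For the p53 pathway, Trp53 was lower in co-culture on feeders labelled p53-defective (153 ± 11 against 293 ± 6 CPM; 158, 160 and 141 against 289, 300 and 291; log2 fold change -0.94 ± 0.09), Mdm2 fell 7.48-fold (82 ± 4.5 against 613 ± 23 CPM, -2.90 ± 0.07) and Cdkn1a was not called (-0.16 ± 0.11, adjusted p = 0.205). Of 35 p53 targets, 26 fell and 6 rose (median -1, adjusted p = 0.001; adjusted p = 0.2 with an estimated correlation). Btg2 stood at -3.08 ± 0.08 and Sesn2 at -3.27 ± 0.10. With scaling on ES-specific genes these directions turned: Trp53 to 2.50, Cdkn1a to 3.28, Mdm2 to 0.54, Btg2 to 0.35, Sesn2 to 0.16 (not called) and the list median to 2.43, where the list call ended (adjusted p = 0.962). All 24 G2/M genes fell (median -1.99, adjusted p = 6.21e-08; adjusted p = 0.0938 with an estimated correlation). The cyclin gene Ccna2 stood at -2.26 ± 0.07 and Ccnb1 at -2.81 ± 0.09; the other scaling turned them to 1.18 and 0.62 and the list to 1.44, where its call ended (adjusted p = 0.978). The difference between the co-culture and the feeder effect was 1.19 ± 0.16 for Cdkn1a (adjusted p = 6.75e-07) and -1.49 ± 0.10 for Mdm2 (adjusted p = 4.4e-12), which turned to 1.54 when scaled on ES-specific genes.

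Contractile, adhesion and glycolytic genes rose on feeders labelled p53-defective, beside the rise of feeder-specific genes. Of 24 focal adhesion genes, 18 rose and 4 fell (median 0.85, adjusted p = 0.000222; adjusted p = 0.265 with an estimated correlation), with zyxin (Zyx) at 2.11 ± 0.06 and Tgfb1i1 at 2.33 ± 0.10. Of 20 actin, SRF and YAP targets, 15 rose and 4 fell (median 1.43, adjusted p = 0.00149; adjusted p = 0.538 with an estimated correlation). Ankrd1 stood at 4.44 ± 0.09 and the tropomyosin gene Tpm1 at 2.55 ± 0.13. Of 23 glycolysis and hypoxia genes, 18 rose and 4 fell (median 1.71, adjusted p = 7.88e-05; adjusted p = 0.2 with an estimated correlation). Ndrg1 stood at 5.23 ± 0.11 and the triose phosphate isomerase gene Tpi1 at 2.97 ± 0.09. Fibroblast markers were not called as a list (12 rose and 7 fell of 23, median 0.43, adjusted p = 0.108).

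Interferon and immediate early genes were lower. Of 20 interferon response genes, 19 fell and none rose (median -2.74, adjusted p = 8.27e-06; adjusted p = 0.217 with an estimated correlation). Oas2 stood at -7.33 ± 0.15 and Rsad2 at -6.63 ± 0.21. The list of immediate early and dissociation stress genes holds 14 immediate early genes, which are induced within minutes of a stimulus, and 6 heat shock genes. Of these 20, 16 fell and 2 rose, with 12 and 1 among the immediate early genes (median -2.61, adjusted p = 0.000869; adjusted p = 0.278 with an estimated correlation). Fos stood at -7.13 ± 0.10 (5.2 ± 0.67 against 731 ± 7 CPM) and Fosb at -8.00 ± 0.16. Of 19 FGF-ERK targets, 13 fell and 4 rose (median -1.28, adjusted p = 0.0272; adjusted p = 0.538 with an estimated correlation). Egr1 stood at -4.61 ± 0.13 and the feedback inhibitor Spry2 at -3.70 ± 0.11. The same lists scaled on ES-specific genes had medians of 0.69, 0.82 and 2.16. Fos, Egr1, Egr2 and Ier3 are in both the immediate early and the FGF-ERK list, so their calls are not separate results in any comparison. Large rises were those of the uroplakin gene Upk3b (727 ± 54 against 0.483 ± 0.21 CPM), the membrane glycoprotein gene Gpm6a (171 ± 2.9 against 0.275 ± 0.078 CPM) and the guanylate-binding protein gene Gbp2b, which was at least 228-fold higher than in ES cells on control feeders, where it had 0 counts. Upk3b (458 ± 180 against 6.5 ± 1.1 CPM) and Gpm6a (log2 fold change 6.64) were also higher in the feeders labelled p53-defective alone. Large falls included the angiotensin receptor gene Agtr2 (-8.35 ± 0.35) and Apod (-7.08 ± 0.18).

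Across all 15389 genes the feeder effect and the co-culture effect of the p53 label correlated at r = 0.37 (Spearman's rho 0.236), with 2466 genes higher in both (2025.3 if independent), 2979 lower in both (2759.3 if independent) and 4087 called in opposite directions. Genes are not independent replicates, so no p is given. Over the 47 feeder-specific genes r was 0.585.

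The third comparison, of ES cells after feeder removal with ES cells on control feeders, asks what differs without the feeders. The label does not say whether these ES cells were grown on control feeders and then separated from them or grown without feeders. Pluripotency transcripts were modestly higher after removal. Sox2 rose 1.35-fold (343 ± 16 against 255 ± 6.1 CPM, n = 3 per group, adjusted p = 0.0017). Pou5f1 stood at 739 ± 20 against 557 ± 23 CPM (log2 fold change 0.41 ± 0.11, adjusted p = 0.00613) and Nanog at 572 ± 34 against 472 ± 19 CPM (0.28 ± 0.10, adjusted p = 0.0193). The call of Pou5f1 ended without replicate 1 of ES cells on control feeders (0.33) or replicate 1 after removal (0.33). That of Nanog ended with no filter (0.23) or a stricter filter on low counts (0.22), without replicate 1 (0.21), 2 (0.21) or 3 (0.26) of ES cells on control feeders, and without replicate 1 (0.22) or 3 (0.19) after removal. None of the 3 was called when scaled on ES-specific genes (Sox2 0.17, Pou5f1 0.14, Nanog 0.02).

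Of 14 core pluripotency genes, 13 rose and none fell (median 0.50, adjusted p = 0.000957; adjusted p = 0.118 with an estimated correlation). Scaled on ES-specific genes, 6 of the 13 ES-specific members were higher and 1 lower (median 0.18). Rif1 stood at 1.51 ± 0.10 and L1td1 at 0.98 ± 0.08. Of 23 naive genes, 17 rose and 2 fell (17 and 3 adjusted over the list alone; median 0.52, adjusted p = 0.000512; adjusted p = 0.137 with an estimated correlation). On that scale 8 of the 17 ES-specific members were higher and 3 lower (median 0.28). The adhesion gene Jam2 stood at 1.35 ± 0.09 and the DNA methylation cofactor Dnmt3l at -1.08 ± 0.10. Among ES-specific genes, the NODAL antagonist Lefty2 (1.59 ± 0.11), Tdh (1.47 ± 0.09), Trh (1.37 ± 0.09), the metalloprotease gene Mep1b (2.11 ± 0.13) and Mcf2 (1.83 ± 0.12) were among the large rises. The tubulin gene Tuba3b (-1.53 ± 0.09), Tex19.2 (-1.35 ± 0.10) and the T-box gene Eomes (-0.98 ± 0.09) fell. Of 24 G2/M genes, 17 rose and none fell (median 0.36, adjusted p = 5.05e-05; adjusted p = 0.22 with an estimated correlation). Kif11 stood at 0.96 ± 0.07.

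Hypoxia and glycolysis genes formed the group with the smallest list p. Of 23, 20 fell and none rose (median -0.98, adjusted p = 2.24e-10; adjusted p = 0.105 with an estimated correlation). The oxygen sensor gene Egln3 fell by 2.57 ± 0.11 on the log2 scale (11.2 ± 0.39 against 66.8 ± 6.3 CPM), the vasodilator peptide gene Adm by 2.53 ± 0.16, the mitophagy gene Bnip3 by 1.98 ± 0.10 and Ndrg1 by 1.79 ± 0.11. Large falls were those of the nitric oxide synthase gene Nos2 (-3.43 ± 0.19), the growth factor gene Pgf (-3.40 ± 0.18) and Ndufa4l2 (-3.01 ± 0.27). Of 20 immediate early and dissociation stress genes, 15 fell and 2 rose, with both rises among the 6 heat shock genes (median -0.57, adjusted p = 0.000499; adjusted p = 0.354 with an estimated correlation). Fos stood at -1.52 ± 0.07, Jun at -1.22 ± 0.08 and Zfp36, whose protein degrades short-lived RNA, at -1.14 ± 0.07.

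Fibroblast markers were lower but still present after removal: 14 of 22 fell and 1 rose (median -0.36, adjusted p = 0.00264; adjusted p = 0.401 with an estimated correlation). The mesenchymal transcription factor gene Prrx1 stood at -0.98 ± 0.12 (61 ± 5.8 against 121 ± 6.1 CPM) and Twist1 at -0.81 ± 0.11. Fn1 fell 1.39-fold (1640 ± 59 against 2290 ± 80 CPM, adjusted p = 0.00596) and Itga5 1.31-fold (adjusted p = 0.000679), while Itgav was not called (-0.05 ± 0.12, adjusted p = 0.783, with overlap between the groups). Itgb1 stood at -0.15 ± 0.08 (adjusted p = 0.133), called without replicate 3 after removal (-0.24), with a stricter filter on low counts (-0.21), in a fit of only these 2 groups (-0.15) and when scaled on ES-specific genes (-0.41). Of 16 integrin genes, 9 fell and 1 rose (median -0.42, adjusted p = 0.016; adjusted p = 0.548 with an estimated correlation), a call that ended when scaled on ES-specific genes (-0.68). Trp53 stood at 374 ± 26 against 293 ± 6 CPM (0.35 ± 0.09, adjusted p = 0.00208; 0.09 and not called when scaled on ES-specific genes) and Cdkn1a fell 1.66-fold (adjusted p = 1.67e-05). Mdm2 stood at -0.12 ± 0.07 (adjusted p = 0.128), called without replicate 3 of ES cells on control feeders (-0.20), without replicate 1 after removal (-0.20), with a stricter filter (-0.18), in a fit of only these 2 groups (-0.12) and when scaled on ES-specific genes (-0.39). With edgeR, 8001 of 15389 genes were called, 3924 higher and 4077 lower, of which 417 and 825 changed at least 2-fold. Scaled on ES-specific genes, 1512 were higher and 6806 lower.

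**Figure D3:**
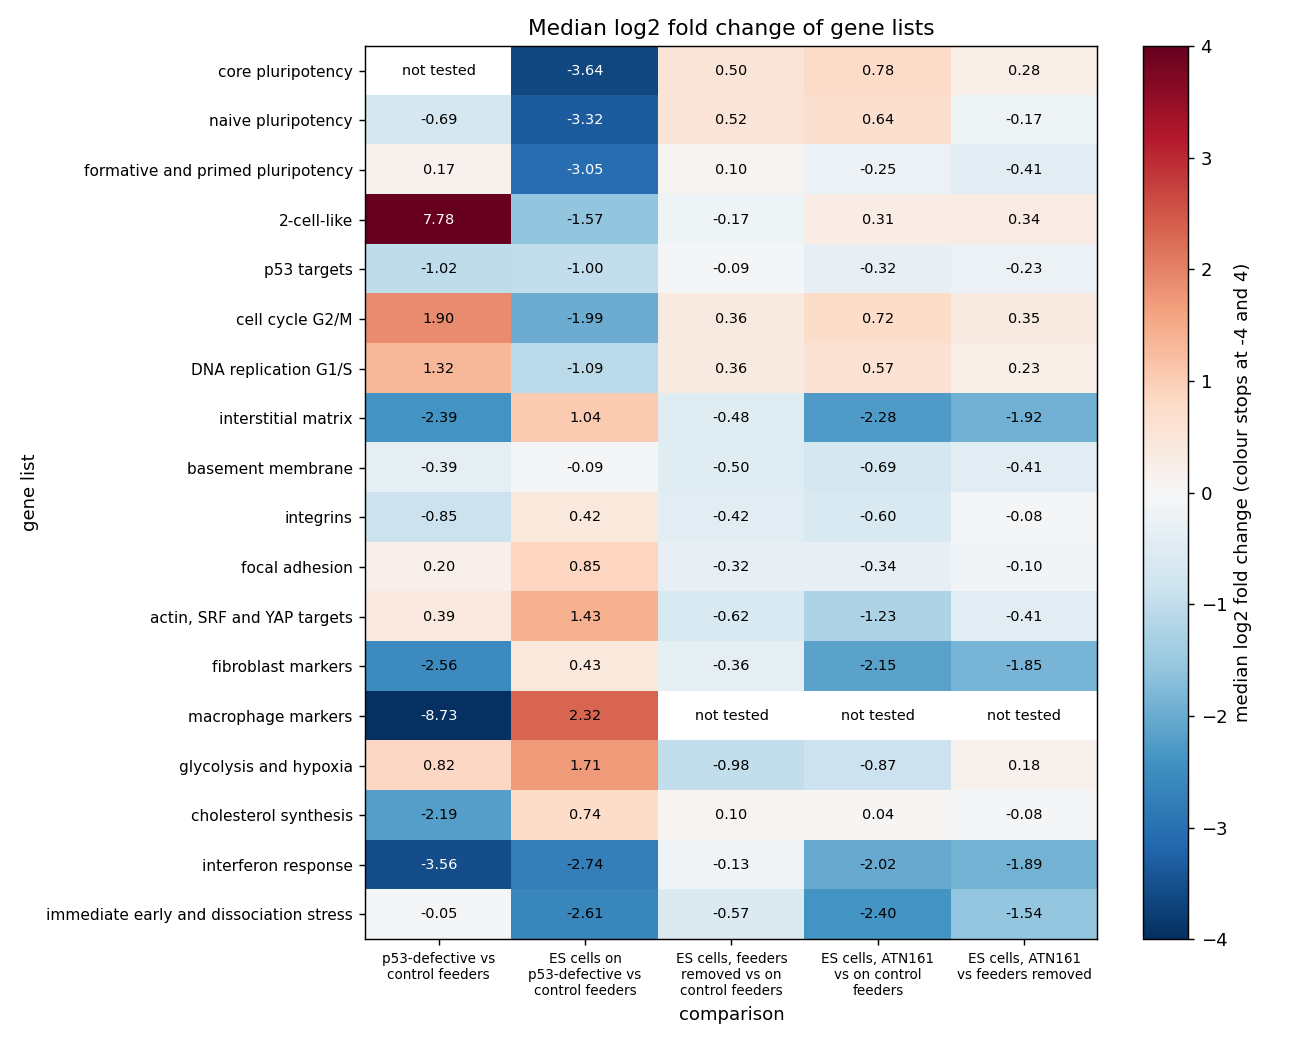
Median log2 fold change of 18 gene lists (lines) in the 5 pairwise comparisons (columns), with lists of fewer than 5 measured members marked as not tested. Interstitial matrix genes had medians of -2.28 and -1.92 with ATN161, and naive pluripotency genes a median of -3.32 in ES cells on feeders labelled p53-defective.

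The fourth comparison, of ES cells with ATN161 in place of feeders with ES cells on control feeders, asks about integrin inhibition together with the absence of feeders. Pluripotency factor RNA was higher with ATN161: Nanog rose 1.98-fold (933 ± 16 against 472 ± 19 CPM, n = 3 per group, adjusted p = 1.25e-08), Sox2 1.83-fold (468 ± 8.4 against 255 ± 6.1 CPM, adjusted p = 4.35e-07) and Pou5f1 1.7-fold (949 ± 48 against 557 ± 23 CPM, adjusted p = 1.4e-05). Scaled on ES-specific genes these rises were smaller and still called, at 0.55 (Nanog), 0.44 (Sox2) and 0.33 (Pou5f1) on the log2 scale. Of 14 core pluripotency genes, 12 rose and 1 fell (median 0.78, adjusted p = 0.00188; adjusted p = 0.0982 with an estimated correlation). Of 23 naive genes, 18 rose and 2 fell (median 0.64, adjusted p = 0.00146; adjusted p = 0.114 with an estimated correlation), Klf2 among those that fell (-0.60 ± 0.09). On ES-specific scaling, 9 of 13 ES-specific core members were higher and 1 lower (median 0.36), and 9 of 17 naive members higher and 3 lower (median 0.25). The epithelial transcription factor gene Grhl2 also fell (-0.68 ± 0.09). Among large rises were Tcf15 (1.54 ± 0.10), a bHLH factor gene, the water channel gene Aqp3 (1.54 ± 0.10), the ES cell Ras gene Eras (1.47 ± 0.09) and the germ cell helicase gene Ddx4 (1.43 ± 0.13).

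Immediate early and dissociation stress genes had the lowest list median. All 20 were called, 17 lower and 3 higher, with all 14 immediate early genes lower and the 6 heat shock genes split (median -2.40, adjusted p = 1.28e-10; adjusted p = 0.056 with an estimated correlation). Fosb fell from 561 ± 77 to 0.256 ± 0.18 CPM, Fos from 731 ± 7 to 5.8 ± 0.63 CPM, Egr1 from 1100 ± 80 to 27.9 ± 0.87 CPM and Egr2 from 22.5 ± 3.4 to 0.39 ± 0.20 CPM; Jun fell by 4.36 ± 0.09 and Zfp36 by 4.24 ± 0.09 on the log2 scale. Of 19 FGF-ERK targets, 15 fell and 2 rose (median -0.56, adjusted p = 5.58e-06; adjusted p = 0.114 with an estimated correlation). The cyclin gene Ccnd1 stood at -1.83 ± 0.08.

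**Figure D4:**
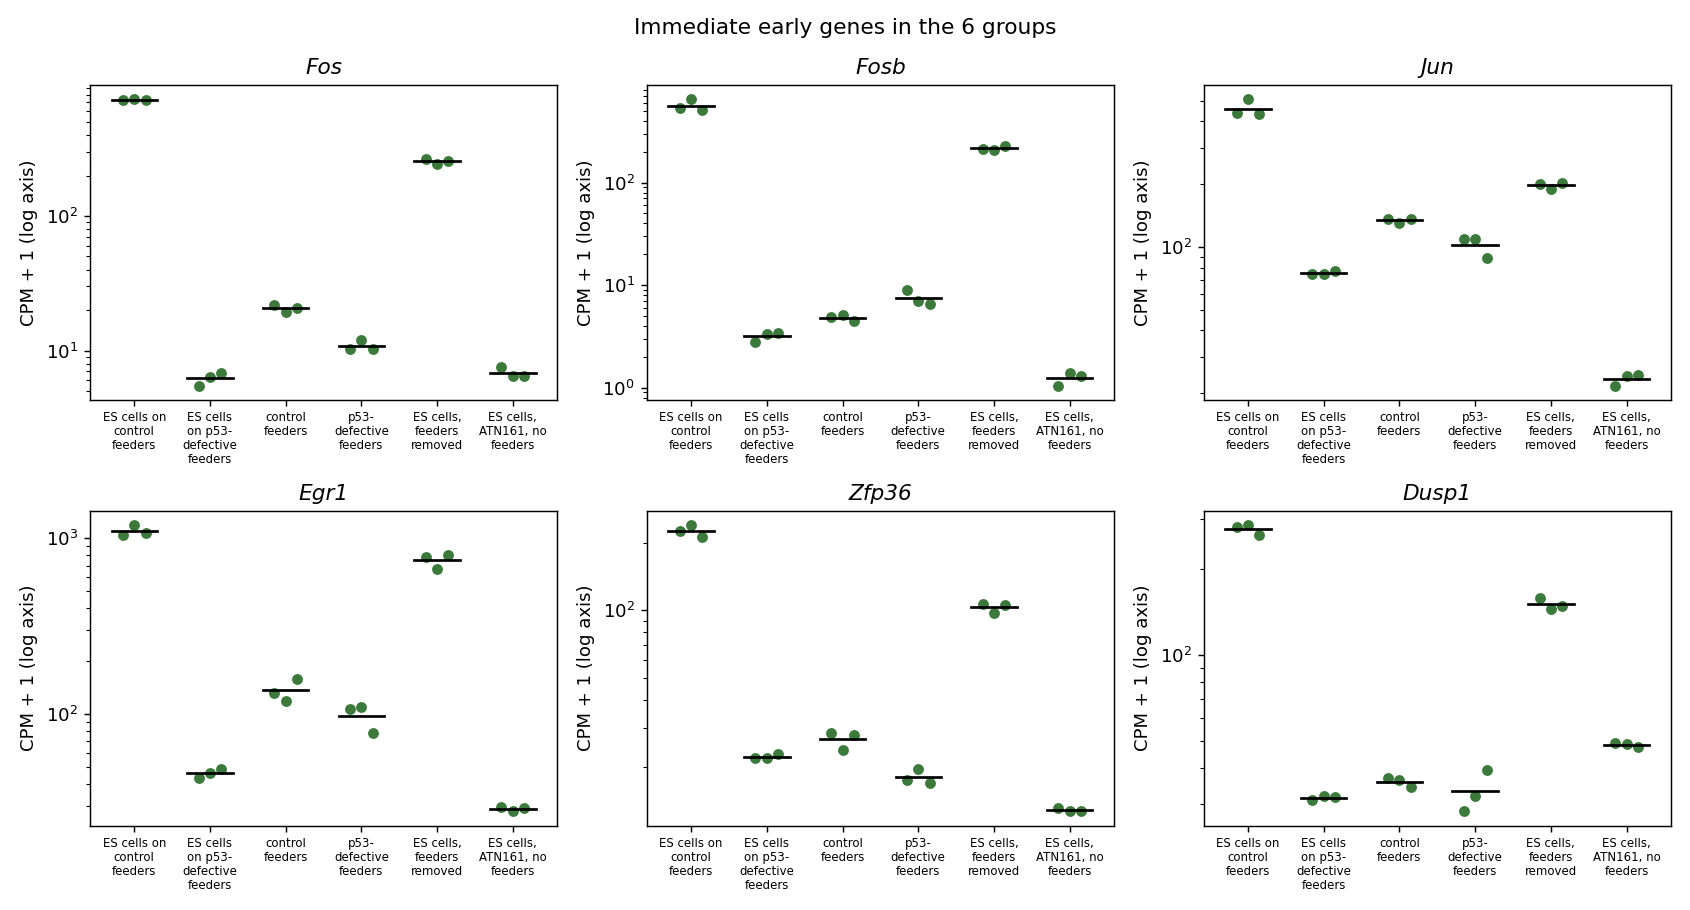
Levels of immediate early genes in the 6 groups as TMM-scaled CPM on a log axis, with 1 point per library and a line at the mean of 3. Fos had means of 731 CPM in ES cells on control feeders, 255 CPM after feeder removal, 5.8 CPM with ATN161 and 19.6 CPM in control feeders alone.

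Matrix, fibroblast and secreted protein genes fell together. All 22 measured fibroblast markers fell (median -2.15, adjusted p = 1.04e-14; adjusted p = 0.0403 with an estimated correlation). The intermediate filament gene Vim stood at -1.76 ± 0.08 and Tbx15 at -2.69 ± 0.13. All 27 interstitial matrix genes fell (median -2.28, adjusted p = 4.57e-17; adjusted p = 0.0982 with an estimated correlation). The collagen gene Col3a1 stood at -3.37 ± 0.15 and the lysyl oxidase-like gene Loxl2 at -2.89 ± 0.12. Of 19 senescence-associated secretion genes, 18 fell and none rose (median -2.12, adjusted p = 3.96e-10; adjusted p = 0.0403 with an estimated correlation). The chemokine gene Cxcl1 stood at -4.47 ± 0.15. Of 20 actin, SRF and YAP targets, 16 fell and 1 rose (17 and 1 adjusted over the list alone; median -1.23, adjusted p = 1.44e-06; adjusted p = 0.212 with an estimated correlation). Ccn1 stood at -3.70 ± 0.14 and the receptor kinase gene Axl at -2.36 ± 0.09. All 20 interferon response genes fell (median -2.02, adjusted p = 2.1e-12; adjusted p = 0.056 with an estimated correlation). Oasl2 stood at -2.27 ± 0.08 and Rsad2 at -3.28 ± 0.14.

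Fn1 fell 1.74-fold (1320 ± 45 against 2290 ± 80 CPM, adjusted p = 3.7e-05), Itgb1 1.42-fold (adjusted p = 1.41e-05) and Itgav 1.65-fold (adjusted p = 3.51e-05). Itga5, the α chain of the receptor that ATN161 binds, stood at -0.11 ± 0.09 (adjusted p = 0.29, with overlap between the groups; called at -0.54 when scaled on ES-specific genes and at -0.20 in a fit of only these 2 groups). Of 16 integrin genes, 12 fell and 1 rose (median -0.60, adjusted p = 0.00134; adjusted p = 0.31 with an estimated correlation). Itga11 stood at -3.36 ± 0.15. Of 24 G2/M genes, 23 rose and none fell (median 0.72, adjusted p = 1.2e-09; adjusted p = 0.056 with an estimated correlation). Nusap1 stood at 1.17 ± 0.09. Of 35 p53 targets, 20 fell and 5 rose (median -0.32, adjusted p = 0.00591; adjusted p = 0.183 with an estimated correlation). The secreted factor gene Gdf15 stood at -2.17 ± 0.14, Btg2 at -1.44 ± 0.08, Cdkn1a at -1.20 ± 0.12 and Mdm2 at -0.86 ± 0.07, while Trp53 stood at 0.55 ± 0.09 (adjusted p = 1.34e-05; 0.12 and not called when scaled on ES-specific genes). Of 23 glycolysis and hypoxia genes, 17 fell and 2 rose (median -0.87, adjusted p = 6.63e-06; adjusted p = 0.0982 with an estimated correlation). Egln3 stood at -2.40 ± 0.11 and Bnip3 at -2.06 ± 0.10. With edgeR, 9483 of 15389 genes were called, 5176 higher and 4307 lower, of which 278 and 1960 changed at least 2-fold. Scaled on ES-specific genes, 737 were higher and 7942 lower.

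The fifth comparison sets ATN161 in place of feeders against feeder removal. The labels do not say whether these cultures matched in time or medium, and genes high in feeders were measured in both. The limb gene Prrx1 stood at 19.3 ± 1.5 CPM with ATN161 and 61 ± 5.8 CPM after removal, against 314 CPM in control feeders alone. Feeder-specific genes, which both groups served to choose, stood at 5.57 ± 0.12% and 8 ± 0.26% of their level in feeders alone. The 1 gene at least 32-fold higher in feeders stood at 1.23% and 1.17%. It also stood at 1.2% in ES cells on control feeders, so it did not track feeder RNA there and cannot compare the 2 groups. Whether the RNA of feeder-specific genes came from feeders left behind or from the ES cells was not tested. The falls of fibroblast, matrix, interferon and secreted protein genes below can therefore not be assigned to ATN161 rather than to less feeder RNA. Nanog rose 1.63-fold (933 ± 16 against 572 ± 34 CPM, n = 3 per group, adjusted p = 2.38e-06) and Sox2 1.36-fold (468 ± 8.4 against 343 ± 16 CPM, adjusted p = 0.0011). Pou5f1 stood at 949 ± 48 against 739 ± 20 CPM (0.36 ± 0.11, adjusted p = 0.0123), a call that ended without replicate 2 (0.32) or 3 (0.33) after removal and when scaled on ES-specific genes (0.18). Neither the core list (8 of 14 rose and 3 fell, 8 and 4 adjusted over the list alone, median 0.28, adjusted p = 0.649) nor the naive list (8 of 23 rose and 10 fell, 8 and 12 adjusted over the list alone, median -0.17, mean 0.03, adjusted p = 0.839) was called. The RNA-binding protein gene Lin28a fell by 1.04 ± 0.08 and the de novo methyltransferase gene Dnmt3b by 0.64 ± 0.07 on the log2 scale.

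Trophectoderm genes and single ES-specific genes changed. Of 10 measured trophectoderm genes, 7 rose and none fell (median 1.03, adjusted p = 0.00624; adjusted p = 0.0913 with an estimated correlation), with the keratin genes Krt8 (1.74 ± 0.10), Krt18 (1.75 ± 0.18) and Krt19 (1.33 ± 0.15) and the homeobox gene Esx1 (1.57 ± 0.17). Against ES cells on control feeders, Krt8 (-1.63 ± 0.10), Krt18 (-1.87 ± 0.18) and Krt19 (-1.89 ± 0.14) were lower after feeder removal, so these rises rest largely on the low level in that group. With ATN161 Krt8 stood at 15.5 CPM, against 4.64 after removal and 14.4 on control feeders. Among ES-specific genes, Tuba3b (2.07 ± 0.09), the epithelial factor gene Elf3 (1.64 ± 0.09), the meiosis gene Stra8 (1.64 ± 0.08), Gtsf1 (1.54 ± 0.10), the phosphatase gene Dusp9 (1.42 ± 0.07) and Eomes (1.39 ± 0.09) were among the large rises. The NODAL pathway genes Lefty2 (-2.03 ± 0.11) and Lefty1 (-1.52 ± 0.11), Trh (-1.99 ± 0.09) and Tdh (-1.23 ± 0.09) fell. Both this comparison and the third use the removal libraries, so that opposite changes in them are not separate findings. Tuba3b stood at 109 CPM with ATN161 against 75.1 on control feeders, and Trh at 23.4 against 35.8.

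Immediate early genes were again lower: 17 of 20 in the list with dissociation stress fell and 1 rose, all 14 immediate early genes among the former (median -1.54, adjusted p = 1.09e-11; adjusted p = 0.0497 with an estimated correlation). Fosb stood at -9.69 ± 0.20 (0.256 ± 0.18 against 216 ± 9.6 CPM), Fos at -5.45 ± 0.10 and Egr1 at -4.75 ± 0.13. Of 20 interferon response genes, 19 fell and none rose (median -1.89, adjusted p = 9.15e-14; adjusted p = 0.0497 with an estimated correlation). Rsad2 stood at -3.26 ± 0.14. Of 19 senescence-associated secretion genes, 15 fell and 1 rose (median -2.01, adjusted p = 1.9e-08; adjusted p = 0.0497 with an estimated correlation). Cxcl1 stood at -3.34 ± 0.16 and the interleukin 33 receptor gene Il1rl1 at -3.14 ± 0.11. All 21 measured fibroblast markers fell (median -1.85, adjusted p = 1.41e-14; adjusted p = 0.0497 with an estimated correlation). Dcn stood at -2.54 ± 0.11 and S100a4 at -2.10 ± 0.12. Of 27 interstitial matrix genes, 26 fell and none rose (27 and none adjusted over the list alone; median -1.92, adjusted p = 2.79e-17; adjusted p = 0.0913 with an estimated correlation). Col3a1 stood at -2.53 ± 0.14.

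Among adhesion genes, Itgb1 fell 1.28-fold (adjusted p = 8e-04) and Itgav 1.6-fold (adjusted p = 0.000104), and integrins were not called as a list (6 fell and 2 rose of 15, median -0.08, adjusted p = 0.252). Itga5 stood at 0.28 ± 0.09 (adjusted p = 0.0085), a call that ended without replicate 2 after removal (0.23) and when scaled on ES-specific genes (0.10). Fn1 stood at -0.32 ± 0.14 (1320 ± 45 against 1640 ± 59 CPM, adjusted p = 0.0549), called with DESeq2 size factors (-0.33), a stricter filter (-0.34), the DESeq2 Wald test (-0.33), a fit of only these 2 groups (-0.36) and scaling on ES-specific genes (-0.50). Of 35 p53 targets, 18 fell and 5 rose (19 and 6 adjusted over the list alone; median -0.23, adjusted p = 0.0312; adjusted p = 0.32 with an estimated correlation). Mdm2 stood at -0.73 ± 0.07, Cdkn1a at -0.47 ± 0.11 and Trp53inp1 at -0.88 ± 0.09, and Trp53 not called (0.20 ± 0.09, adjusted p = 0.0576; called at 0.16 in a fit of only these 2 groups). Of 24 G2/M genes, 17 rose and 1 fell (median 0.35, adjusted p = 0.000122; adjusted p = 0.159 with an estimated correlation). Cdk1 stood at 0.83 ± 0.09 and Plk1 at 0.67 ± 0.07. With edgeR, 8527 of 15389 genes were called, 4406 higher and 4121 lower, of which 530 and 1399 changed at least 2-fold. Scaled on ES-specific genes, 2138 were higher and 5377 lower.

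The effect of feeders labelled p53-defective on the co-culture and that of ATN161 against feeder removal, which share no library, were set side by side to ask whether they move the same genes. Across 15389 genes they correlated at r = 0.077 (Spearman's rho 0.08), with 1918 genes higher in both (1614.2 if independent), 2277 lower in both (1925.7 if independent) and 3086 in opposite directions. Over the 408 ES-specific genes r was 0.41 (rho 0.428), and 0.409 when scaled on them, where 53 genes were higher in both (38.8 if independent), 90 lower in both (53.6 if independent) and 43 opposite. As before, genes are not independent replicates.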

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

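The tests of a mesothelial profile, strain variants, feeder share, naive genes, mixing and loss of feeder RNA were chosen only after the result was seen; those of body region, harvest handling and regrouped libraries were written before. The p53 effect was tested for a difference between co-culture and feeders alone (co-culture effect minus feeder effect), and 11327 of 15389 genes differed with edgeR, 5975 higher and 5352 lower. When scaled on ES-specific genes, 13058 were higher and 505 lower. Single genes differed on the log2 scale as follows: Trp53 -2.25 ± 0.13, Cdkn1a 1.19 ± 0.16, Mdm2 -1.49 ± 0.10, Fn1 2.11 ± 0.20, Itga5 1.13 ± 0.12, Itgb1 1.77 ± 0.11, Itgav 0.83 ± 0.17, Btg2 -1.31 ± 0.11, Oasl2 2.33 ± 0.21, Sesn2 -1.94 ± 0.13 and Ndrg1 2.24 ± 0.14. Apod at 7.22, Lum at 7.08 and Usp17la at -10.07 had 0 counts (Apod) or 1 to 3 counts in a feeder group, so these fitted sizes are not reliable. Lists lower in co-culture than the feeder effect alone had median differences of -3.91 (core pluripotency), -2.91 (naive), -3.05 (formative and primed), -8.48 (2-cell-like; -5.47 with genes at 0 counts set to a bound), -3.86 (ES cell markers), -3.77 (G2/M), -2.35 (DNA replication), -1.64 (FGF-ERK targets) and -1.93 (immediate early and dissociation stress genes). Lists higher had 3.09 (interstitial matrix), 1.48 (integrins), 0.63 (focal adhesion), 1.64 (matrix remodelling), 2.29 (feeder-secreted factors), 3.64 (fibroblast markers; 3.51 with such bounds), 9.95 (macrophage markers; 6.73 with such bounds), 0.99 (glycolysis and hypoxia) and 2.73 (cholesterol synthesis). Scaling on ES-specific genes turned the direction of Trp53 (0.77), Mdm2 (1.54), Btg2 (1.71) and Sesn2 (1.08). It also turned naive (0.12), formative and primed (0.36) and DNA replication genes (0.68), FGF-ERK targets (1.38) and immediate early and dissociation stress genes (1.09), with these list calls kept. With an estimated correlation these calls ended for formative and primed genes (adjusted p = 0.229), DNA replication (0.198), FGF-ERK targets (0.403), immediate early and dissociation stress genes (0.198), interstitial matrix (0.198), integrins (0.449), focal adhesion (0.449), matrix remodelling (0.312), feeder-secreted factors (0.198), fibroblast markers (0.0755), glycolysis (0.449) and cholesterol synthesis (0.254). The glycolysis call ended without replicate 2 of ES cells on control feeders (1.03), replicate 3 of ES cells on feeders labelled p53-defective (1.10), control feeder replicate 3 (1.02), and replicates 1 (1) and 3 (0.95) of the feeders labelled p53-defective. Since ES cell RNA is in co-culture only, a difference of this kind also holds any change of the mixture. Of 14 core pluripotency genes 5 were called lower and 9 were not called. Of 18 ES cell markers 7 were lower and 11 not called, and of 23 naive genes 13 were lower, 1 higher and 9 not called. Only 3 core genes, 4 ES cell markers and 10 naive genes reached 1 CPM in a feeder group. For the other members of these lists the difference largely repeats the fall in co-culture.

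Other groupings of the libraries were fitted in the same way. For the difference of effects, 2 of 70 groupings drawn of 200 possible called as many genes as the real 11327. These were the real grouping and the exchange of the co-culture labels as a whole (12085), which sums the 2 effects. Groupings that kept 1 of the 2 pairs of groups whole called up to 7199. A random grouping was thus excluded for this count, but the count also holds each effect alone. It cannot decide whether the 2 effects differ. For the 5 pairwise comparisons only 1 of 10 groupings, the real one, called as many genes, and 10 are too few for a share under 0.05. The real counts were 11433, 12829, 8001, 9483 and 8527, and the highest other grouping called 0, 0, 0, 0 and 1.

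The feeders labelled p53-defective differed from control feeders in 11433 genes. No value in the tables excluded a tested explanation. Body region or stage of the feeders may contribute, because the 36 Hox genes present had a median absolute log2 fold change of 2.72 (10 higher, 24 lower; 99.78th percentile of matched lists, whose median was 1.34). Strain variants may contribute for 7 genes, as predicted or pseudogene models made up 7 of 93 genes present in 1 feeder group only against 199 of 10343 (odds ratio 4.26, p = 0.00206 in Fisher's exact test). A mesothelial profile cannot be told apart from a change within fibroblasts. Of 19 markers 78.9% rose (15 higher), just short of the 80% set for it. Since that cutoff was set after the result was seen, missing it decides nothing. Krt8 at -2.21 and Krt18 at -4.40 fell, but both rose in co-culture on these feeders (2.46 and 2.13). Of the markers, 4 are also in the trophectoderm list. Their median of 3.64 lay at the 100th percentile of matched lists, with Msln at 775 ± 96 against 28.1 ± 3.1 CPM. The p53 deficiency that the labels name stays open and was not tested apart from these explanations.

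ES cell genes were lower in the co-culture on feeders labelled p53-defective. A larger share of feeder RNA may account for part of this, since feeder-specific genes rose by a median of 1.78 on the log2 scale in all 3 libraries. That rise was 1.43 with a 4-fold cutoff and 3.61 with a 32-fold cutoff (1 gene). ES-specific genes fell by 3.40, but that fall is the pattern itself and no separate support. The feeder-specific genes include Acta2, which stood at 4890 CPM in this co-culture against 754 in the same feeders alone. Their rise is therefore not a measure of share alone. Whether naive genes fell beyond that share cannot be told apart: 17 naive members lay -0.42 from other ES-specific genes (p = 0.136 in a permutation test over random lists). Mixing of unchanged feeder and ES cell RNA was excluded as the whole account, because 1190 genes were at least 2-fold above the feeders labelled p53-defective and both groups of ES cells without feeders (796 of them also in plain CPM), against 81 on control feeders. A response of feeders or ES cells to each other stays open and was not tested.

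Immediate early genes were lower with ATN161 in place of feeders than on control feeders. Of the 17 fallen members of the list, 14 were immediate early and 3 heat shock genes. Of the 17, 12 were at least 2-fold higher in ES cells on control feeders than in control feeders alone, and 16 were higher at all. Loss of feeder RNA at the level of feeders alone was thus excluded as the whole account for those 12. Feeders in co-culture were not measured apart from ES cells, so loss of RNA that feeders made only there stays open. Handling of the cells at harvest cannot be told apart, because 3 of 6 heat shock genes were lower (Hspa1a -3.13, Hspa1b -1.72, Dnajb1 -0.39) and the other 3 higher (Hspa8 0.34, Hsph1 0.55, Hspb1 0.52). Integrin inhibition by ATN161 stays open and was not tested apart from the harvest or other differences between the cultures. The Y chromosome genes Ddx3y, Kdm5d, Uty and Eif2s3y were also lower with ATN161 than on control feeders (-2.13, -2.85, -2.31 and -1.41). Ddx3y stood at 3.69 CPM with ATN161, 16.1 on control feeders and 1.26 in those feeders alone. Whether the ES cells of these groups were otherwise alike was not tested.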

How the results depend on the processing

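The tests within ES-specific genes for feeder removal and ATN161, the specific genes in TMM-scaled CPM and the lists with all tested members were chosen only after the data were seen; the other alternatives were planned. Libraries held 15.12 to 19.83 M counts, so that genes at a few counts have wide errors, and without 1 library the remaining 2 of a group carry its spread. Replicates with the same number in different groups correlated at -0.07 to 0.223. Different numbers were not compared, so whether the numbers pair the libraries was not settled. An alternative pseudocount was planned for TPM or FPKM only and was not run, since counts were tested. For all values below that moved, the cause was not tested unless it is stated.

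Requiring a change of at least 2-fold left 5553 genes for the feeders, 7305 for ES cells on the 2 kinds of feeder, 1242 for feeder removal, 2238 for ATN161 against control feeders, 1929 for ATN161 against feeder removal and 7481 for the difference of the p53 effects, fewer by construction. Scaling on ES-specific genes gave 13933, 8318, 8679 and 7515 genes for the 4 comparisons of ES cell cultures and 13563 for the difference of effects, and 13387, 1836, 3206, 2100 and 13081 at least 2-fold. With only ES-specific genes tested, the counts were 294, 255, 226 and 293, of which 123, 23, 8 and 43 were at least 2-fold; with only feeder-specific genes they were 36 and 20 for ES cells on the 2 kinds of feeder. These tests held fewer genes. With a stricter filter on low counts, changes of at least 2-fold numbered 858 for feeder removal and 1260 for ATN161 against feeder removal, again over fewer genes. List calls numbered 7 with an estimated correlation and 145 with fry, against 85. Feeder-specific genes moved by 1.43 (4-fold, 238 genes), 3.61 (32-fold, 1 gene only) and 2.22 (TMM-scaled CPM) and ES-specific genes by -3.09, -3.72 and -3.04. The correlation of the feeder and co-culture effects (0.37) was 0.585 over feeder-specific genes, 0.32 with no filter and 0.359 with limma-voom, and 0.359 to 0.381 without 1 library. That of the co-culture and ATN161 effects (0.077) was 0.41 over ES-specific genes, 0.052 with no filter, 0.112 with the stricter filter and 0.091 scaled on ES-specific genes, and 0.065 to 0.092 without 1 library.

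Directions turned with scaling on ES-specific genes, which moved the median of all genes in co-culture to 3.25. In ES cells on the 2 kinds of feeder these were Trp53 2.50, Cdkn1a 3.28, Mdm2 0.54, Klf2 0.10, Ccna2 1.18, Ccnb1 0.62, Btg2 0.35, Sesn2 0.16, Usp17la 1.15 and Zscan4d 1.49, and with only ES-specific genes tested Klf2 0.10 and Zscan4d 1.49. Medians of lists that turned, all still below that of all genes, were naive 0.10, formative 0.36, 2-cell-like 1.86, p53 targets 2.43, G2/M 1.44, DNA replication 2.35, FGF-ERK targets 2.16, interferon 0.69 and immediate early 0.82. Of these, the calls ended for 2-cell-like genes (adjusted p = 0.326), p53 targets (0.962), G2/M (0.978) and DNA replication (0.341). In the difference of effects these were Trp53 0.77, Mdm2 1.54, Btg2 1.71, Sesn2 1.08, naive 0.12, formative 0.36, DNA replication 0.68, FGF-ERK targets 1.38 and immediate early 1.09. With only feeder-specific genes tested, Col5a2 turned to -0.20.

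With limma-voom, 296 of 296 tests of named genes kept direction and side of the threshold, and with DESeq2 size factors 294 of 296. Scaled on ES-specific genes, 204 of 234 tests of named genes and 61 of 89 lists did, and 14 of each turned direction. Without 1 library, 1854 of 1872 did, and 708 of 726 for lists. Counts of genes called ranged without 1 library from 11084 to 11494 (feeders), 12503 to 12733 (ES cells on the 2 kinds of feeder), 6861 to 7421 (feeder removal), 8230 to 8796 (ATN161 against control feeders) and 7199 to 7821 (ATN161 against feeder removal). With a replicate block, 295 of 296 named genes and 102 of 103 lists kept theirs.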

Other observations

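The tests behind these values were chosen only after the data were seen, except those of Hox genes. Co-culture on feeders labelled p53-defective held RNA that neither part held at that level. The nitric oxide synthase gene Nos2 stood at 85.4 CPM there, against 1.65 in the same feeders alone, 2.21 after feeder removal and 2.04 with ATN161. It was also above its parts on control feeders, at 24 CPM against 0 in those feeders alone. The alarmin gene Il33 stood at 210 CPM (9.56 in the feeders alone), the smooth muscle actin gene Acta2 at 4890 (754), the calponin gene Cnn1 at 195 (15) and the lactate dehydrogenase gene Ldha at 3090 (525). Of 23 glycolysis and hypoxia genes 18 lay at least 2-fold above all 3 parts, against 4 on control feeders, and of 20 actin, SRF and YAP targets 8 did.

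Some RNA of control feeders was nearly absent from the co-culture made with them. Lgr5 stood at 0.261 CPM in ES cells on control feeders against 144 in control feeders alone, Lyz2 at 0.484 against 113 and Ctss at 0.179 against 30.1. The limb gene Prrx1, by contrast, stood at 121 against 314 CPM. Among Hox genes in the feeders, Hoxc6 (-6.88 ± 0.21) was lower and Hoxa4 (3.26 ± 0.25) and Hoxa2 (2.17 ± 0.18) higher in those labelled p53-defective, where Hoxd13 had 0 counts against 50 CPM in control feeders and Hoxd10 stood at 0.0204 against 7.01 CPM. Genes of the Y chromosome were lower with ATN161 than after feeder removal, Ddx3y at -1.88 ± 0.16 (adjusted p = 6.18e-09), Kdm5d at -2.10 ± 0.21, Uty at -2.07 ± 0.20 and Eif2s3y at -1.23 ± 0.15. Against ES cells on control feeders they were lower too, at -2.13, -2.85, -2.31 and -1.41. In feeders labelled p53-defective alone, Ddx3y and Kdm5d had 0 counts against 1.26 and 0.48 CPM in control feeders, and Eif2s3y was not called (0.31 ± 0.22, adjusted p = 0.195, with overlap between the groups).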
